A study of Arabidopsis thaliana with 19 samples.

How the data were processed

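RNA was measured in 19 libraries of Arabidopsis Col-0: 4 young rosettes, 4 mature rosettes, 3 roots, 4 flowers and 4 stems. Per the labels the libraries are polyA-selected and stranded, and were sequenced in paired reads on a NovaSeq 6000. The values in each file are raw counts per gene, as deposited by the authors, 1 library per file, with no scaling and no pooling of replicates. Per the submitters' processing notes, Bowtie2, DESeq2 and the TAIR10 build were used, with no versions and no roles. The counting program, its strand setting, its handling of reads with several matches and the annotation release are not given in the sources used here, nor is whether a count is a read or a read pair. Only the count files were used here, not the DESeq2 output.

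Each file lists 32833 genes, of which 28657 have a count in some library. Names and coordinates come from the TAIR10.1 reference by locus code, which matched 32548 genes and left 285 without a name. Starts are given counted from 1. Total counts run from 25853436 (mature rosette 2) to 120458563 (young rosette 1). Levels in CPM are counts scaled by library size times the TMM factor of the library. At these depths a floor of 3 counts is 0.0329 to 0.134 CPM in single libraries. Genes below about 0.1 CPM are therefore near the limit of detection. Labels were checked with marker genes, correlations between libraries (log2 CPM with a prior count of 1) and principal components. Copies of a library were looked for with a chi-square per degree of freedom over genes with a summed count of at least 10, and the lowest value within an organ is 5.05, so no 2 libraries are copies.

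The 5 comparisons are stem, young rosette, flower and root each against mature rosette, and stem against flower. They, the gene lists, the tests and the rule for naming genes were fixed before the data were examined. The test is the quasi-likelihood F-test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with robust dispersion. It was fitted to all 19 libraries with organ as the only term, TMM scaling and the filterByExpr filter (minimum count 10, minimum total count 15), which left 23484 genes. P-values were adjusted with Benjamini-Hochberg over these genes, and a gene is called at an adjusted p under 0.05. Log2 changes come with the SE of the fit. For a gene with no count in one organ, the fold is a bound against a floor of 3 counts over the group. The rank of such a gene among the largest changes comes from the fit and not from this bound. Means of CPM come with the SD between libraries.

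Whole lists were tested with camera in limma, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 40 lists of a comparison. The same test with an estimated correlation is printed beside each call that it ends. A list was tested with at least 3 tested members. The 40 lists hold 485 members. Those for photosynthesis are NDH complex (nuclear), NDH complex (plastid), NDH assembly and RNA maturation, PGR5 and PGRL, photosystem I and LHCI, photosystem II, LHCII, cytochrome b6f with plastocyanin and ATP synthase, ferredoxin and FNR of leaf type and of root type, thylakoid regulation, Calvin-Benson cycle, photorespiration, chlorophyll synthesis and C4-acid metabolism. Those for tissues are secondary wall, lignin monomers, cuticular wax, guard cell, phloem and procambium, shoot meristem, floral homeotic, pollen, tapetum, seed storage, root endodermis and suberin, root hair, root nutrient uptake and root triterpene clusters. Those for state and defence are aliphatic glucosinolates, indolic glucosinolates, flavonoids, senescence, salicylate defence, jasmonate, cell cycle, circadian clock, phase change and flowering time, heat shock and hypoxia.

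The NDH to photosystem I transcript ratio is the mean log2(CPM + 1) of the nuclear NDH list minus that of the photosystem I and LHCI list, per library. Stems were compared with each other organ by an exact two-sided permutation test on the difference of means (scipy 1.17.1, numpy 2.4.6, Python 3.11.15), adjusted over the 4 comparisons. Figures were drawn with matplotlib 3.10.9.

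Genes were named by a rule. It takes the 6 genes with the largest rise and the 6 with the largest fall per comparison, among called genes with a symbol, a mean of at least 10 CPM in the higher organ and no overlap between libraries. For each list described it takes up to 4 called members with the largest change, those that go the other way, and those that did not pass, as values. It also takes any member of the nuclear NDH, PGR5 and PGRL, and both ferredoxin and FNR lists, and 20 genes given as levels. Where a fold depends on 1 library, levels are given in its place. The text departs from this rule in choices made after the values were seen. Of the called members the rule takes from a list, it gives mostly 1 or 2, those whose change depended least on 1 library. Members left out so include NYE2, and GPAT5, MYB12 and SEN1 are named without a fold in 1 comparison each. For most lists, members that did not pass are given as counts only. Those left out so include FD1, CAD4, LHCB7, AP3, AG, CRC and SUP for stem against mature rosette, HSP18.2 for young rosette, and LHCB4.3, LAP6 and TKPR1 for flower, and of these FD1, CAD4, AG, CRC, SUP and TKPR1 change sign under some alternative. The members named therefore look steadier than the members the rule takes. List counts, medians and tests use all members.

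The test was tested on simulated data with known changes. In the stem against mature rosette setting it recovered 2%, 26%, 84% and 82% of genes changed 1.5, 2, 4 and 8-fold, with 4.85% of calls false. In the other comparisons 28% to 36% of 2-fold and 84% to 94% of 4-fold changes were recovered, with 2.83% to 5.98% of calls false. In each setting only 50 of 23484 genes were changed at each fold, besides a short list. In the data 12967 genes are called for stem against mature rosette. Recovery, false calls and scaling were thus not tried with so many changed genes, and the rates need not hold there. A list shifted by design passed and an unshifted one did not in each setting. The genes were simulated independently, whereas members of real lists correlate (estimated at 0.294 for nuclear NDH and 0.813 for photosystem I). This outcome therefore does not tell how camera behaves under such correlation.

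The alternatives fixed beforehand were RLE scaling, no filter on low counts, nuclear genes only, a fit on only both organs compared, the replicate number as a block, each replicate left out in turn, camera with an estimated correlation, glmTreat against a 2-fold change, and DESeq2 1.42.0 with the Wald test. For the ratio they were a pseudocount of 0.1, medians, summed CPM, no filter and a block. Alternatives added after the data were seen are library size as the only scaling, a clock score as covariate, both 4th libraries of stem and flower left out, and stems 1 and 4 left out. The clock score is the mean log2(CPM + 1) of CCA1, LHY and RVE8 minus that of TOC1, PRR5, ELF4, LUX and FKF1. Proteins and siliques were not analysed here.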

Results

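The libraries come from 5 organs of Arabidopsis Col-0: young rosettes (4), mature rosettes (4), roots (3), flowers (4) and stems (4). The question is how transcripts for the chloroplast NDH complex and for the rest of photosynthesis are divided among the organs. The NDH complex passes electrons from ferredoxin to plastoquinone and is held on photosystem I by the antenna proteins LHCA5 and LHCA6. Rosettes grew with 8 h light and 16 h dark at 120 µmol photons per m2 per s, for 3 weeks (young) or 5 weeks (mature). Roots grew with 8 h light at 50 µmol photons on vertical MS agar for 6 weeks, and stems and flowers with 12 h light and 12 h dark at 120 µmol. Organ therefore goes with light regime, medium and age, and stems alone were extracted with a different lysis solution. A score of morning minus evening clock genes also differs between organs. It is −1.98 to −1.51 in mature rosettes 2 to 4 but 8.16 in mature rosette 1. In other organs it is 2.5 to 7.97, except in stem 4 (−1.75) and flower 4 (−2.71). All comparisons with mature rosette, not only that of young rosettes, therefore carry this difference. Each replicate had its own tray and was grown at another time than the rest. Siliques, named in the series design, were not analysed here.

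Total counts per library run from 25853436 to 120458563, and 23484 genes were tested. Within an organ, log2 CPM of any 2 libraries correlate across genes at r = 0.936 to 0.989, where genes are not independent replicates. Levels in CPM are counts scaled by library size times the TMM factor. Marker genes follow the labels. RBCS1A stands at 27320 ± 1560 CPM (mean ± SD) in young rosettes, 15350 ± 2850 in mature rosettes, 5898 ± 1250 in stems, 4158 ± 1250 in flowers and 74.4 ± 52.3 in roots. The petal gene AP3 is at 165 ± 43 CPM in flowers and 0.835 ± 0.934 in stems, the endodermal gene CASP1 at 67.9 ± 21.8 in roots, and the xylem cellulose synthase gene CESA8 at 514 ± 173 in stems against 36.2 ± 11.5 in roots. The first principal component holds 38.8% of the variance and the second 31.7%.

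Transcripts of the nuclear genes for the NDH complex are most abundant in rosettes, intermediate in stems, lower in flowers and nearly absent in roots. Over 20 genes, mean log2(CPM + 1) is 7.43 in young rosettes, 7.13 in mature rosettes, 6.32 in stems, 4.85 in flowers and 0.84 in roots. The 16 genes for photosystem I and its antenna give 11.6, 11.56, 9.85, 8.56 and 3.5 in the same order. NDHL (chromosome 1, 26687202 to 26688384) is at 279 ± 14.7 CPM in young rosettes, 253 ± 6.25 in mature rosettes, 134 ± 22.1 in stems, 30.8 ± 5.06 in flowers and 0.06 ± 0.0775 in roots. PNSB1 is at 390 ± 33.8, 275 ± 25.4, 190 ± 47.5, 53.8 ± 8.65 and 0.545 ± 0.147 CPM. NDHO (chromosome 1, 28129828 to 28131077) is at 61 ± 11.6 in stems and 154 ± 60.7 in mature rosettes, where replicate 1 has 245 and the other replicates 122 to 125. LHCA5 is at 156 ± 13.3 in stems and 226 ± 37.2 in mature rosettes, and PSAD1 at 1318 ± 213 and 3658 ± 569. Both copies of the plastid gene ndhB have 0 counts in all libraries, so no value is given for it.

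The NDH to photosystem I transcript ratio is the difference between both means, in log2 units. It is −4.17 ± 0.07 in young rosettes, −4.43 ± 0.12 in mature rosettes, −3.53 ± 0.12 in stems, −3.71 ± 0.19 in flowers and −2.66 ± 0.59 in roots (mean ± SD). Stems stand 0.90 above mature rosettes, a 1.87-fold higher ratio, with no overlap between libraries (exact two-sided permutation p = 0.0286, adjusted p = 0.0571). Against young rosettes the difference is 0.64, or 1.56-fold, again with no overlap (exact permutation p = 0.0286, adjusted p = 0.0571). The smallest p that 4 against 4 libraries allow is 0.0286, and none of the 4 comparisons passes 0.05 after adjustment. Stems and flowers differ by 0.18, within the spread between replicates (exact permutation p = 0.2, adjusted p = 0.2). Stems are 0.87 below roots (exact permutation p = 0.0571, the smallest possible with 3 roots, adjusted p = 0.0762). Root transcripts are so few that this sign depends on the pseudocount: 0.1 in place of 1 gives 0.80 above roots. With list medians in place of means, stems stand 1.08 above mature rosettes, 0.74 above young rosettes and 0.44 above flowers, and all of these pass (exact permutation, adjusted p = 0.0381 each). For both rosettes the unadjusted p is already the smallest possible with means, so medians add no evidence there. Their adjusted p is lower only because stem against flower reaches the smallest p too.

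**Figure D1:**
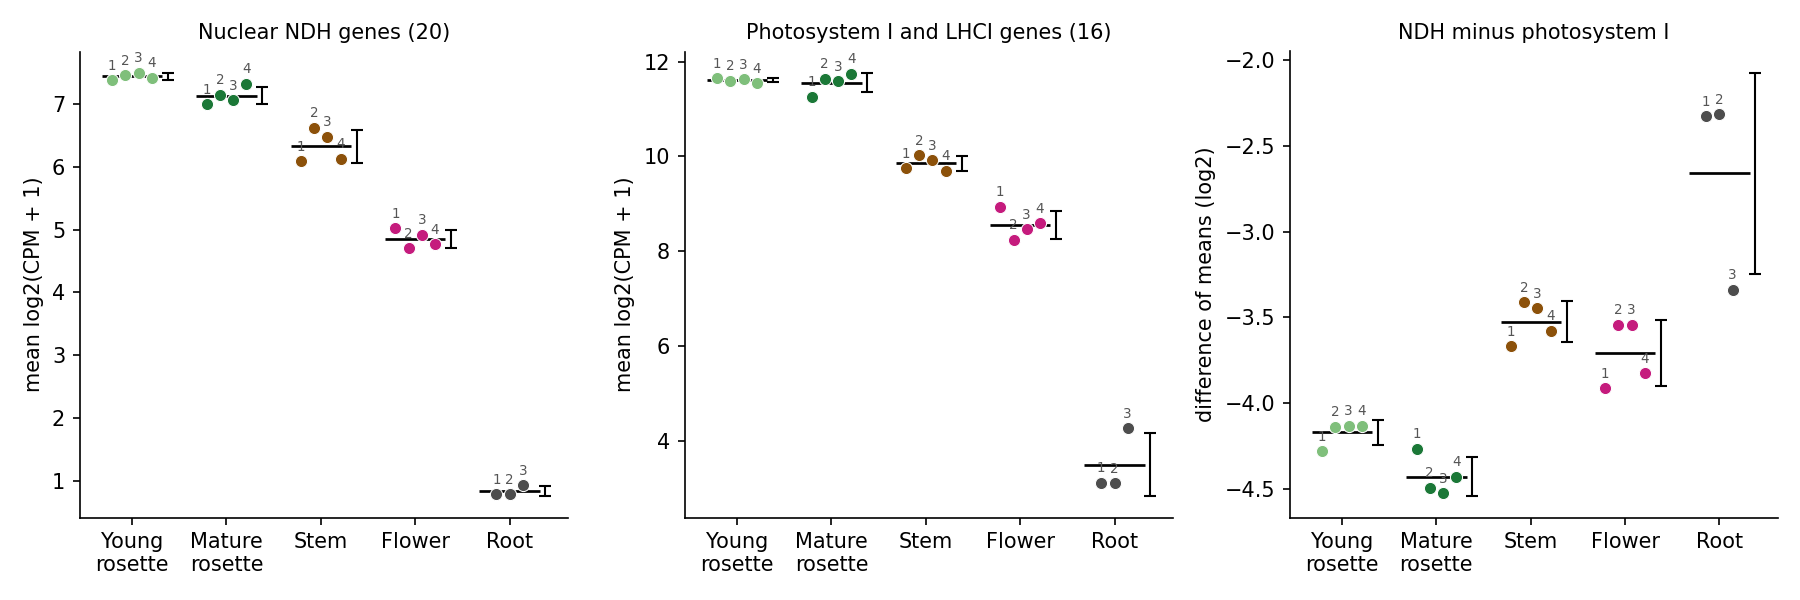
Mean log2(CPM + 1) of 20 nuclear NDH genes, of 16 photosystem I and LHCI genes, and the difference of both, for each library (points numbered by replicate, black line for the organ mean, error bar for the SD). The stem difference, −3.53 on average, lies above every rosette library, while both sets of transcripts are lower in stems than in rosettes.

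Stems carry leaves and flowers upward, and their fibres and vessels are stiffened by thick lignified walls. Genes for cellulose, xylan and lignin are far higher in stems than in mature rosettes, such as the cellulose synthase gene CESA4 (1060 ± 359.6 against 7.11 ± 3.99 CPM, mean ± SD, n = 4 each) and the lignin gene COMT1 (1682 ± 351 against 90.9 ± 9.14), though with an estimated correlation the secondary wall list has adjusted p = 0.145 and the lignin list adjusted p = 0.254. Genes of photosystem I and the NDH complex are lower, by a median log2 change of −1.75 and −0.87 (both adjusted p = 0.371 with an estimated correlation). Meristem and floral regulators are higher and cell cycle genes lower, such as MCM7 (0.904 ± 0.274 against 16 ± 4.61 CPM), with adjusted p = 0.112, 0.193 and 0.254 with an estimated correlation.

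Of 23484 genes, 12967 differ between stem and mature rosette, 6767 higher and 6200 lower, of which 4712 and 4223 by at least 2-fold. The largest increases include SND1 (chromosome 1, 11865229 to 11867154), a switch for fibre walls, at 48.6 ± 12.1 CPM in stems and 0 in mature rosettes, at least 2070-fold. AGL6 is at 25.8 ± 10.1 against 0 (at least 1270-fold) and the wall-loosening gene XTH12 at 18.9 ± 7.62 against 0 (at least 822-fold). The meristem gene STM is at 259 ± 36.6 against 0.0207, the flowering signal FT at 348 ± 201 against 0.0478, and the peroxidase gene PER64 at 279 ± 124 against 0.0312 CPM. On the lower side are the receptor kinase gene CRK21 (chromosome 4, 12177734 to 12180936; 0.0546 in stems against 80 ± 25.6 CPM), TCL2 (0.0227 against 19.2 ± 10.3) and NUDT24 (0.0258 against 27.3 ± 20.5). CYP71B29 is at 0.0384 against 14.6 ± 1.23, the glucosinolate-breakdown gene ESM1 at 2.4 ± 2.18 against 1018 ± 51.1, and the rosette homeobox gene ATH1 at 0.0958 against 37.3 ± 4.78 CPM.

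Of the 20 nuclear NDH genes 14 fell, with a list median log2 change of −0.87 (adjusted p = 0.000481, and adjusted p = 0.371 with an estimated correlation). PNSB3 (−2.10 ± 0.24, log2 change ± SE), PNSL1 (−1.92 ± 0.26) and LHCA6 (−1.86 ± 0.20) fell most. NDHM (−0.17), NDHN (−0.20), NDHS (−0.21), NDHT (0.15), NDHV (0.28) and PNSB2 (0.47) did not pass. All 16 photosystem I and LHCI genes fell, with a median of −1.75 (adjusted p = 8.69e-07, and adjusted p = 0.371 with an estimated correlation), PSAK by 2.28 ± 0.23. Of the genes for NDH assembly and RNA maturation 7 of 10 fell (median −0.88, adjusted p = 0.00701, and adjusted p = 0.388 with an estimated correlation). The 10 plastid NDH genes did not move as a list (adjusted p = 0.439), and polyA selection leaves few plastid transcripts to count. For the PGR5 and PGRL route of cyclic electron flow the list did not pass either (adjusted p = 0.765). There PGRL1A fell (−0.44 ± 0.17), PGR5 did not pass (−0.43), and PGRL1B rose (0.40 ± 0.16). The PGRL1A call is lost without mature rosette 2, 3 or 4 or stem 1 or 4 (adjusted p = 0.0642 to 0.0982), and the PGRL1B call without mature rosette 1 or 2 or stem 1, 2 or 4 (0.0711 to 0.124). With only both organs fitted, both 4th libraries left out, or stems 1 and 4 left out, PGRL1A has 0.147, 0.0972 and 0.284 and PGRL1B 0.116, 0.104 and 0.311. PGRL1A is also lost with library size as the only scaling (0.154), and PGRL1B with a replicate block (0.055), RLE scaling (0.0654), no filter on low counts (0.059) and DESeq2 (0.0638).

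All 11 photosystem II genes fell (median −1.26, adjusted p = 0.000115, and adjusted p = 0.371 with an estimated correlation), among them PSBQ2 (−2.39 ± 0.33). In LHCII 13 of 15 fell (median −2.04, adjusted p = 0.000166, and adjusted p = 0.429 with an estimated correlation). LHCB4.3 rose (0.80 ± 0.32), a call lost without mature rosette 1, 2 or 3 or stem 1, 2 or 3 (adjusted p = 0.058 to 0.14), with a replicate block (0.0546), RLE scaling (0.0565), only both organs fitted (0.065), the clock score (0.129) and DESeq2 (0.052). LHCB1 and RBCS copies are alike, and how reads shared between copies were counted is not given in the sources used here, so values for single copies are uncertain. For cytochrome b6f, plastocyanin and ATP synthase 6 of 8 fell (median −1.18, adjusted p = 0.00236, and adjusted p = 0.371 with an estimated correlation), with ATPD at −2.21 ± 0.18. Leaf-type ferredoxin and FNR genes fell in 7 of 8 cases (median −1.31, adjusted p = 0.00169, and adjusted p = 0.193 with an estimated correlation). The root-type list did not pass (adjusted p = 0.397), though its member FD3 rose (2.2 ± 0.22). All 16 chlorophyll synthesis genes fell (median −1.78, adjusted p = 1.17e-07, and adjusted p = 0.112 with an estimated correlation), DVR by 4.00 ± 0.24. In the Calvin-Benson cycle 12 of 20 fell and CP12-3 rose (median −0.89, adjusted p = 0.00322, and adjusted p = 0.587 with an estimated correlation). Without both stem 1 and stem 4 that list has adjusted p = 0.0534 and CP12-3 0.075. The lists for photorespiration (2 of 12 rose and 4 fell, median −0.087, adjusted p = 0.407), thylakoid regulation (adjusted p = 0.397) and C4-acid metabolism (adjusted p = 0.785) did not pass.

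Secondary wall genes rose in 20 of 21 cases, all but XCP1 (0.67), with a median of 6.31 (adjusted p = 2.53e-16, and adjusted p = 0.145 with an estimated correlation). The xylan gene IRX15 (7.53 ± 0.35) and the cellulose synthase gene CESA4 (7.22 ± 0.44) are examples. In the lignin monomer pathway 13 of 14 rose (median 2.87, adjusted p = 9.92e-08, and adjusted p = 0.254 with an estimated correlation), COMT1 by 4.21 ± 0.27. In phloem and procambium 7 of 8 rose, PXY by 2.49 ± 0.32, and APL fell (median 1.08, adjusted p = 0.0353, and adjusted p = 0.254 with an estimated correlation). That list has adjusted p = 0.0561 without stem 4, 0.0615 without both 4th libraries, 0.0748 without stems 1 and 4 and 0.0571 with only both organs fitted. APL has 0.265 with library size as the only scaling, 0.0782 with only both organs fitted and 0.0784 without stems 1 and 4. Shoot meristem genes rose in 6 of 9 cases, KNAT2 by 9.16 ± 0.52. The list median is 5.31, or 4.51 with bounds for groups at 0 (adjusted p = 0.000632, and adjusted p = 0.112 with an estimated correlation).

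In the floral homeotic list 11 of 15 rose (median 3.97, or 3.69 with bounds, adjusted p = 0.000481, and adjusted p = 0.193 with an estimated correlation). CAL is at least 352-fold higher. Pollen genes rose in 13 of 16 cases (median 3.90, or 3.36 with bounds, adjusted p = 1.44e-05, and adjusted p = 0.193 with an estimated correlation). Their levels in stems have a median of 2.5% of those in flowers. All 9 seed storage genes rose (median 7.48, adjusted p = 0.0254, and adjusted p = 0.683 with an estimated correlation). Summed, they reach 387 CPM in stem 1 and 316 in stem 4, but 1.42 in stem 2 and 28.7 in stem 3. The list does not pass without stem 1 (adjusted p = 0.0546), stem 4 (0.067), stems 1 and 4 (0.226), both 4th libraries (0.0616) or mature rosette 1 (0.0605), nor with library size as the only scaling (0.0584). Senescence genes rose in 10 of 12 cases, SAG13 by 6.56 ± 0.74 (median 1.91, adjusted p = 0.00891, and adjusted p = 0.371 with an estimated correlation). SEN1 fell.

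Cell cycle genes fell in 17 of 20 cases, MCM7 by 4.12 ± 0.28 and MCM2 by 4.07 ± 0.25 (median −1.82, adjusted p = 2.55e-07, and adjusted p = 0.254 with an estimated correlation). Those for indolic glucosinolates fell in 6 of 9 (median −1.64, adjusted p = 0.0107, and adjusted p = 0.254 with an estimated correlation), MYB34 by 3.35 ± 0.35. In all, 19 of 40 lists pass, 8 higher and 11 lower. Adjusted over the list alone, the counts for these lists are the same except that all 21 secondary wall genes rise and 7 of the 8 cytochrome list fall.

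**Figure D2:**
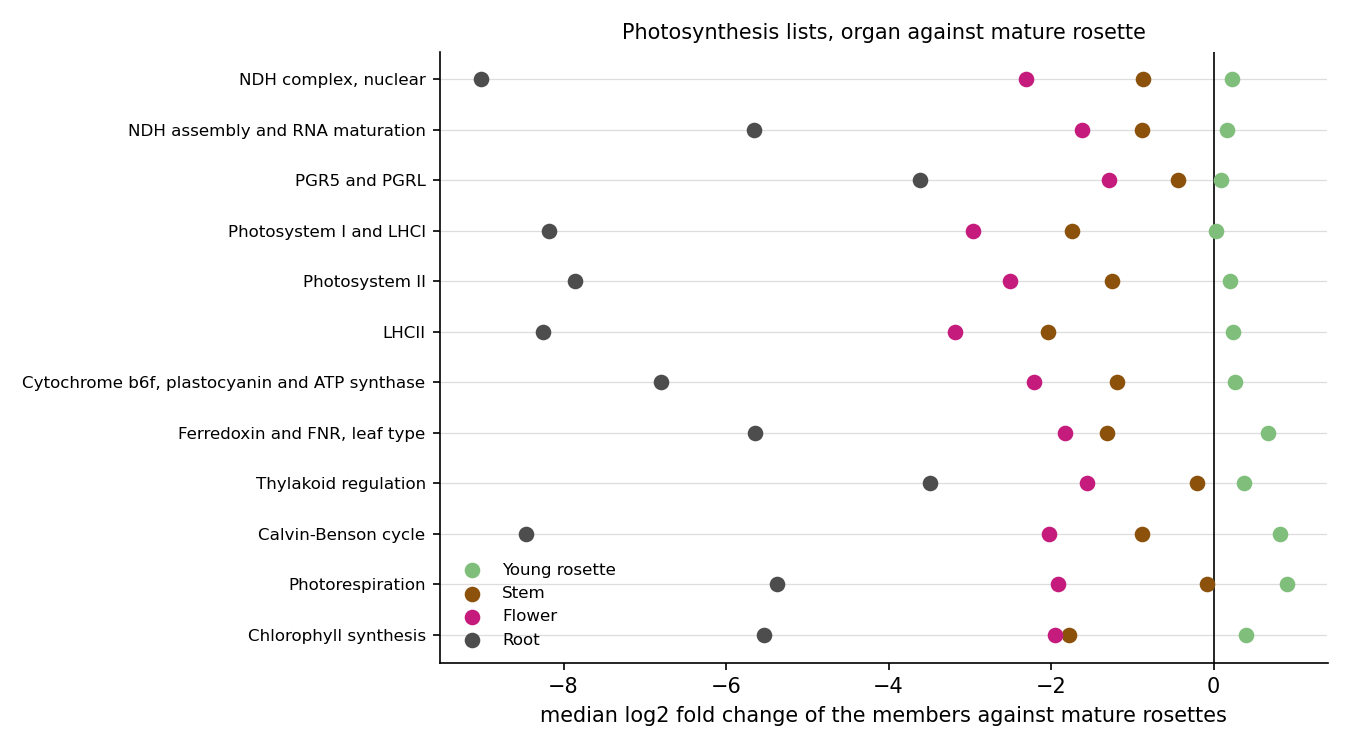
Median log2 change against mature rosette of 12 photosynthesis lists, for young rosette, stem, flower and root. The nuclear NDH list stands at −0.87 in stem beside −1.75 for photosystem I and LHCI, and the root medians of both are −9.02 and −8.18.

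A rosette matures over weeks in which early leaves stop growing and defences build up. Young rosettes have more transcripts than mature ones for carbon fixation, photorespiration, lignin, wax and heat shock proteins, though each of these lists has adjusted p = 0.531 with an estimated correlation. Examples are GLDP1 of the glycine decarboxylase (8257 ± 2328 against 1791 ± 1065 CPM, mean ± SD, n = 4 each) and PAL1, which opens the lignin pathway (759 ± 291 against 55.6 ± 27.6). Transcripts for salicylate and jasmonate defence are fewer, such as those of the storage protein gene VSP2 (9.82 ± 7.22 against 92 ± 51.7), again with adjusted p = 0.531 for both lists with an estimated correlation. Clock genes also separate the libraries, but with mature rosette 1 beside the young ones. The circadian clock list does not pass (camera, adjusted p = 0.866).

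Between young and mature rosette 7440 genes differ, 3167 higher and 4273 lower, of which 1390 and 2561 by at least 2-fold. With library size as the only scaling 1601 are higher and 6421 lower. Mature rosette 1 resembles the young rosettes. It correlates with them at r = 0.965 to 0.977 and with the other mature rosettes at 0.941 to 0.952, across genes, which are not independent replicates. A score of morning minus evening clock genes is 8.16 in it, 7.13 to 7.97 in young rosettes and −1.98 to −1.51 in mature rosettes 2 to 4. Without it 10060 genes are called. With the clock score as a covariate, an alternative chosen after the data were seen, 2687 genes are called. Among the genes and lists of this comparison it ends the call of the secondary wall list (adjusted p = 0.0875) and those of 14 genes, given here with the log2 change before and after. These are PNSL5 (0.435 and 0.387), PGRL1B (−0.596 and −0.41), CP12-3 (−1.086 and −0.718), PNSB2 (1.201 and 0.774), FBA1 (1.496 and 0.925), LEA3 (4.002 and 2.303), VSP2 (−3.229 and −1.732), HEMA1 (1.619 and 0.849), CESA4 (1.191 and 0.583), WRKY54 (−3.611 and −1.303), MEE14 (−6.101 and −1.687), PORB (−4.323 and −0.727), PRR3 (−7.503 and −1.234) and LFNR2 (−1.245 and 0.108).

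**Figure D3:**
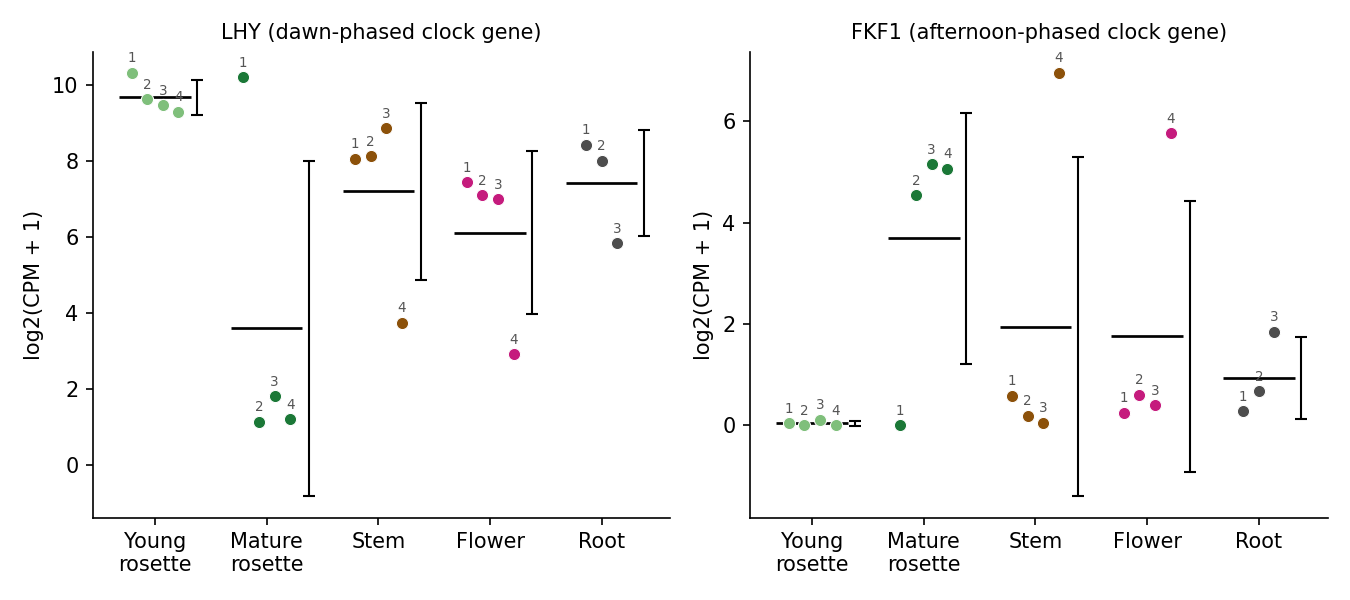
log2(CPM + 1) of the morning gene LHY and the evening gene FKF1 in each library (points numbered by replicate, black line for the organ mean, error bar for the SD). Mature rosette 1, flower 4 and stem 4 stand apart from the other replicates of their organs.

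The largest increases are in ELIP2 (chromosome 4, 8418242 to 8419325), a pigment-binding light-stress gene, at 23.9 ± 5.76 CPM in young and 0.342 ± 0.445 in mature rosettes. SMZ, a repressor of flowering, is at 12.9 ± 9.15 against 0.725 ± 0.401, and the chaperone gene Hop3 at 54.7 ± 9.01 against 3.37 ± 3.82. LEA3 is at 355 ± 88.6 against 22.1 ± 8.32, ASPGB1 at 16.3 ± 8.34 against 1.18 ± 0.342, and the flavonol gene FLS1 at 129 ± 54 against 9.36 ± 0.314 CPM. The largest decreases are in the clock gene PRR3 (chromosome 5, 24197971 to 24201415; 0.062 ± 0.0536 against 14.2 ± 9.36), PCR1 (0.926 ± 0.572 against 83.9 ± 54.7) and the cold-response gene DREB1A (0.536 ± 0.321 against 44.7 ± 28.8). NUDT24 (0.372 ± 0.378 against 27.3 ± 20.5), ST2A (0.16 ± 0.0639 against 11.2 ± 7.52) and MEE14 (2.34 ± 2 against 167 ± 111) complete the 6.

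Among nuclear NDH genes 3 of 20 rose, PNSB2 (1.2 ± 0.29), LHCA6 (0.86 ± 0.19) and PNSL5 (0.43 ± 0.13). PNSL5 has adjusted p = 0.0555 without young rosette 3, and 0.166 with adjusted p = 0.329 with library size as the only scaling. The list passes with a median of 0.23 (adjusted p = 0.0408, and adjusted p = 0.67 with an estimated correlation). It does not without mature rosette 1 (adjusted p = 0.161), mature rosette 3 (0.0642) or young rosette 3 (0.0609), nor with a replicate block (0.0503) or library size as the only scaling (0.167). The photosystem I and LHCI list does not pass (adjusted p = 0.755). In the PGR5 and PGRL route PGRL1B fell by 0.60 ± 0.16, while the list did not pass (median 0.087, adjusted p = 0.999).

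Calvin-Benson genes rose in 14 of 20 cases, FBA1 by 1.5 ± 0.40, and CP12-3 fell (median 0.81, adjusted p = 0.000293, and adjusted p = 0.531 with an estimated correlation). In photorespiration 8 of 12 rose, GLDP1 by 2.21 ± 0.41 and GOX2 by 1.02 ± 0.19 (median 0.90, adjusted p = 0.000305, and adjusted p = 0.531 with an estimated correlation). Leaf-type ferredoxin and FNR genes rose in 4 of 8 cases, FD1 by 2.31 ± 0.43 and FD2 by 1.16 ± 0.24, and LFNR2 fell by 1.25 ± 0.45 (median 0.67, adjusted p = 0.0284, and adjusted p = 0.531 with an estimated correlation). The LFNR2 call is lost without any single young rosette or without mature rosette 2, 3 or 4 (adjusted p = 0.0652 to 0.118), with RLE scaling (0.0535) and with no filter on low counts (0.0509). Of 16 chlorophyll synthesis genes 8 rose, HEMA1 by 1.62 ± 0.35, and PORA and PORB fell (adjusted p = 0.0261, and adjusted p = 0.531 with an estimated correlation). The test for that list points up and its median is 0.40, while its mean is −0.01. The PORB call is lost without young rosette 2, 3 or 4 (adjusted p = 0.063 to 0.0647). Without mature rosette 1 the ferredoxin list and the chlorophyll list both have adjusted p = 0.0655.

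Lignin monomer genes rose in 12 of 14 cases, PAL1 by 3.77 ± 0.42 and 4CL1 by 2.60 ± 0.37 (median 1.71, adjusted p = 9.28e-11, and adjusted p = 0.531 with an estimated correlation). Wax genes rose in 12 of 14, CER3 by 1.57 ± 0.30 (median 0.95, adjusted p = 1.02e-05, and adjusted p = 0.531 with an estimated correlation). Secondary wall genes rose in 11 of 21, CESA4 by 1.19 ± 0.34 (median 0.77, adjusted p = 0.000434, and adjusted p = 0.563 with an estimated correlation). Heat shock genes rose in 5 of 6, with a median of 2.68 (adjusted p = 0.00804, and adjusted p = 0.531 with an estimated correlation). HSP90.1 rose by 2.85 ± 0.68, and by 4.27 without mature rosette 1. Salicylate genes fell in 8 of 16 cases, WRKY54 by 3.61 ± 0.69 (median −1.13, adjusted p = 0.00804, and adjusted p = 0.531 with an estimated correlation). Jasmonate genes fell in 6 of 11, VSP1 by 3.79 ± 0.57 and VSP2 by 3.23 ± 0.64 (median −1.90, adjusted p = 0.00471, and adjusted p = 0.531 with an estimated correlation). In all, 11 of 40 lists pass, 9 higher and 2 lower. Adjusted over the list alone, 15 Calvin-Benson genes, 9 of photorespiration, 13 of secondary wall and 5 of leaf-type ferredoxin and FNR rise, and other counts given here are unchanged.

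Flowers are built by homeotic regulators, hold developing pollen and ovules, and draw on sugar made elsewhere. Pollen genes and floral regulators are far higher in flowers than in mature rosettes, such as VGD1 of pollen tube growth (1850 ± 408 against 0.215 ± 0.252 CPM, mean ± SD, n = 4 each) and SEP2 (222 ± 18.7 against 0.083 ± 0.102). Genes for wax, flavonoids and the cell cycle are also higher, with adjusted p = 0.219, 0.302 and 0.302 with an estimated correlation. Genes of photosystem I and the NDH complex are lower, by a median log2 change of −2.96 (adjusted p = 0.122 with an estimated correlation) and −2.31. Genes of aliphatic glucosinolates are lower too, such as MAM1 (10.1 ± 4.31 against 326 ± 73.9 CPM), with adjusted p = 0.0947 with an estimated correlation.

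Between flower and mature rosette 12324 genes differ, 7164 higher and 5160 lower, of which 5688 and 3324 by at least 2-fold. With library size as the only scaling 10020 are higher and 3295 lower. The largest increases have 0 counts in mature rosettes. They are CYP71B38 (chromosome 3, 15948505 to 15950245; 68.5 ± 36 CPM, at least 3090-fold), CSLD4 (63.3 ± 20.3, at least 2850-fold), GDPD3 (60.8 ± 8.54, at least 2680-fold), MYB101 (59.8 ± 10.7, at least 2640-fold), ATCHX5 (58.1 ± 15.9, at least 2600-fold) and PERK7 (56.7 ± 15.8, at least 2550-fold). CSLD4 and MYB101 act in pollen tubes. The largest decreases are in the carbonic anhydrase gene ACA2 (chromosome 2, 12029666 to 12033096; 0 against 25.4 ± 4.53 CPM, at least 1600-fold), XTH31 (0.0929 ± 0.0239 against 113 ± 46.5) and the defence gene ACD6 (0.728 ± 0.392 against 736 ± 370). PCR1 (0.0868 ± 0.0554 against 83.9 ± 54.7), MSRB6 (0.0767 ± 0.0488 against 65.8 ± 16.8) and RLP19 (0.0318 ± 0.0234 against 28.7 ± 5.77) follow.

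All 20 nuclear NDH genes fell, with a median of −2.31 (adjusted p = 2.7e-13, and adjusted p = 0.0276 with an estimated correlation), PNSL1 by 3.17 ± 0.27 and NDHU by 3.12 ± 0.18. All 16 photosystem I and LHCI genes fell, with a median of −2.96 (adjusted p = 5.75e-12, and adjusted p = 0.122 with an estimated correlation). All 10 NDH assembly genes fell (median −1.62, adjusted p = 1.44e-05, and adjusted p = 0.112 with an estimated correlation), and 6 of 10 plastid NDH genes did (median −1.74, adjusted p = 0.00117, and adjusted p = 0.143 with an estimated correlation). PGR5, PGRL1A and PGRL1B all fell (median −1.29, adjusted p = 0.00636, and adjusted p = 0.0681 with an estimated correlation), PGRL1A by 2.67 ± 0.18. Leaf-type ferredoxin and FNR genes fell in all 8 cases (median −1.83, adjusted p = 1.37e-05), LFNR1 by 2.29 ± 0.22, and the thylakoid regulation genes in 10 of 11 (median −1.56, adjusted p = 3.05e-06), CURT1B by 2.82 ± 0.23. Both hold with an estimated correlation (adjusted p = 0.0276 and 0.0222). The root-type list did not pass (adjusted p = 0.275), though FD3 rose by 2.00 ± 0.21.

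Photosystem II fell in 11 of 11 genes (median −2.50, adjusted p = 1.73e-08, and adjusted p = 0.102 with an estimated correlation), PSBO2 by 3.02 ± 0.19. LHCII fell in 14 of 15 (median −3.18, adjusted p = 1.5e-08, and adjusted p = 0.143 with an estimated correlation). Cytochrome b6f, plastocyanin and ATP synthase fell in 7 of 8, all but ATPC2 (median −2.21, adjusted p = 1.81e-05, and adjusted p = 0.112 with an estimated correlation). All 20 Calvin-Benson genes fell (median −2.02, adjusted p = 3.59e-10, and adjusted p = 0.102 with an estimated correlation), GAPB by 2.52 ± 0.28. Of 12 photorespiration genes 11 fell (median −1.91, adjusted p = 3.42e-07, and adjusted p = 0.102 with an estimated correlation), GGT1 by 2.48 ± 0.22. All 16 chlorophyll synthesis genes fell (median −1.96, adjusted p = 6.13e-09, and adjusted p = 0.0276 with an estimated correlation), CRD1 by 2.66 ± 0.30.

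All 16 pollen genes rose (median 9.61, or 9.42 with bounds, adjusted p = 8.81e-12), and 14 of 15 floral homeotic genes did (median 9.21, or 8.15 with bounds, adjusted p = 2.15e-08), while SEP4 fell by 0.61 ± 0.15. Their examples above stand at less than 1 CPM in mature rosettes. Shoot meristem genes rose in 8 of 9 cases, KNAT2 by 7.65 ± 0.51 (median 3.45, adjusted p = 0.000598). All of these lists have adjusted p = 0.0276 with an estimated correlation. Tapetum genes rose in 6 of 8, AMS at least 44.6-fold (median 8.31, or 5.16 with bounds, adjusted p = 0.00636, and adjusted p = 0.143 with an estimated correlation). Secondary wall genes rose in 19 of 21, FRA8 by 3.55 ± 0.46 (median 1.74, adjusted p = 9.9e-06, and adjusted p = 0.236 with an estimated correlation). Wax genes rose in 11 of 14, MAH1 by 8.17 ± 0.51, and ABCG12 fell (median 1.29, adjusted p = 0.000623, and adjusted p = 0.219 with an estimated correlation). Cell cycle genes rose in 16 of 20, AUR1 by 2.97 ± 0.27 (median 1.4, adjusted p = 0.000552, and adjusted p = 0.302 with an estimated correlation).

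Suberin and endodermis genes rose in 9 of 15, GPAT5 by 9.24 ± 0.96, while CASP1 fell (median 3.61, or 3.24 with bounds, adjusted p = 0.0164, and adjusted p = 0.254 with an estimated correlation). CASP1 is low in both organs, at 0.243 ± 0.159 CPM in mature rosettes and 0 in flowers, against 67.9 ± 21.8 in roots. Flavonoid genes rose in 8 of 13, FLS1 by 4.83 ± 0.57, and PAP1 fell by 1.99 ± 0.65 (median 2.55, adjusted p = 0.0206, and adjusted p = 0.302 with an estimated correlation). Senescence genes rose in 10 of 12, NAP by 3.70 ± 0.46, and SEN1 fell by 2.62 ± 0.46 (median 2.64, adjusted p = 0.00466, and adjusted p = 0.219 with an estimated correlation). All 12 aliphatic glucosinolate genes fell, MYB29 by 7.27 ± 0.68 and MAM1 by 5.02 ± 0.46 (median −3.32, adjusted p = 6.13e-09, and adjusted p = 0.0947 with an estimated correlation). Indolic glucosinolate genes fell in 8 of 9, MYB34 by 4.23 ± 0.36 (median −3.12, adjusted p = 9.18e-06, and adjusted p = 0.0276 with an estimated correlation). Salicylate genes fell in 10 of 16, WRKY54 by 3.68 ± 0.69, and PBS3 rose by 1.94 ± 0.43 (median −1.57, adjusted p = 0.00636, and adjusted p = 0.252 with an estimated correlation). Guard cell genes fell in 4 of 5, MYB60 by 2.01 ± 0.24 (median −1.81, adjusted p = 0.0185, and adjusted p = 0.143 with an estimated correlation). With library size as the only scaling the suberin list has adjusted p = 0.0828 and the flavonoid list 0.0769, and the falls of SEP4 and ABCG12 are lost (0.157 and 0.143). In all, 27 of 40 lists pass, 10 higher and 17 lower. Adjusted over the list alone, 9 plastid NDH, 9 indolic glucosinolate and 11 salicylate genes fall, and 20 secondary wall, 10 suberin, 9 flavonoid and 11 senescence genes rise. The other counts given here are unchanged.

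Roots take up water and minerals through root hairs and an endodermis sealed with suberin, and they have no photosynthesis of note. Genes for nutrient transport, root hairs, suberin and triterpenes are higher than in mature rosettes, such as the sulfate transporter gene SULTR1;2 (385.8 ± 35 CPM in 3 root libraries against 0.233 ± 0.167 in 4 mature rosettes). Genes of photosystem I and the NDH complex are lower, by a median log2 change of −8.18 (adjusted p = 0.0635 with an estimated correlation) and −9.02. Ferredoxin and FNR go from leaf to root types, where the root-type list has adjusted p = 0.184 with an estimated correlation. The root ferredoxin gene FD3 is at 127 ± 20.5 against 9.77 ± 2.78 CPM, and the leaf gene LFNR1 at 11.3 ± 5.12 against 1567 ± 235.

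Between root and mature rosette 13103 genes differ, 7112 higher and 5991 lower, of which 5357 and 4720 by at least 2-fold. With library size as the only scaling 11499 are higher and 4147 lower. The largest increases include THAD (chromosome 5, 19434758 to 19436749), for the triterpene thalianol pathway, at 689 ± 50.6 CPM against 0, at least 30200-fold. The glucosidase gene BGLU21 is at 248 ± 61.4 against 0 (at least 10800-fold), the phosphate transporter gene PHT1;1 at 196 ± 24.9 against 0 (at least 8660-fold) and TPS12 at 165 ± 61.9 against 0 (at least 7180-fold). MLP34 is at 6177 ± 862 against 0.0401 CPM and MLP328 at 5018 ± 399 against 0.0521. The largest decreases have 0 counts in roots in the case of LURP1 (chromosome 2, 6213617 to 6215932; 517 ± 337 CPM in mature rosettes, at least 31400-fold), COR15B (503 ± 356, at least 30300-fold), RGF9 (489 ± 239, at least 28300-fold) and XTH6 (246 ± 267, highest in mature rosette 1). The jasmonate gene LOX2 is at 0.0246 against 1500 ± 551 and ECS1 at 0.0352 against 1940 ± 833 CPM.

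All 20 nuclear NDH genes fell, with a median of −9.02 (adjusted p = 2.86e-20, and adjusted p = 0.0088 with an estimated correlation). NDHU, with no count in roots, is at least 7540-fold lower. All 16 photosystem I and LHCI genes fell, with a median of −8.18 (adjusted p = 8.54e-16, and adjusted p = 0.0635 with an estimated correlation), PSAE1 by 8.88 ± 0.40. What remains of these transcripts is uneven, at 416 summed CPM in root 3 and 158 and 165 in the others. NDH assembly genes fell in 9 of 10 cases (median −5.66, adjusted p = 1.47e-07, and adjusted p = 0.0461 with an estimated correlation), and plastid NDH genes in 9 of 10 (median −3.37, adjusted p = 0.00103, and adjusted p = 0.13 with an estimated correlation). PGR5, PGRL1A and PGRL1B fell (median −3.61, adjusted p = 0.00162, and adjusted p = 0.0268 with an estimated correlation), PGRL1A by 5.68 ± 0.23. All 8 leaf-type ferredoxin and FNR genes fell (median −5.65, adjusted p = 2.82e-08, and adjusted p = 0.0088 with an estimated correlation), LFNR1 by 7.12 ± 0.31. The root types FD3 (3.69 ± 0.24), RFNR2 (2.37 ± 0.27) and RFNR1 (0.92 ± 0.14) all rose (median 2.37, adjusted p = 0.0214, and adjusted p = 0.184 with an estimated correlation).

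All 11 thylakoid regulation genes fell (median −3.49, adjusted p = 1.34e-08), CURT1A by 7.10 ± 0.26, as did all 12 of photorespiration (median −5.37, adjusted p = 5.39e-10) and all 16 of chlorophyll synthesis (median −5.54, adjusted p = 4.02e-12). These hold with an estimated correlation (adjusted p = 0.00395, 0.0378 and 0.0088), as do photosystem II (adjusted p = 0.0423) and the Calvin-Benson cycle (adjusted p = 0.0355). Photosystem II fell in 11 of 11 (median −7.86, adjusted p = 1.31e-11), PSBQ1 by 8.60 ± 0.42, and the Calvin-Benson cycle in 19 of 20 (median −8.46, adjusted p = 8.54e-16), with CP12-3 rising. That rise is lost without mature rosette 1 or 2 or root 2 (adjusted p = 0.061 to 0.186) and with only both organs fitted (0.0997). All 15 LHCII genes fell (median −8.26, adjusted p = 1.13e-12, and adjusted p = 0.0621 with an estimated correlation). Of the cytochrome list 7 of 8 fell, PETE2 by 8.96 ± 0.39, and ATPC2 rose (median −6.81, adjusted p = 8.2e-07, and adjusted p = 0.061 with an estimated correlation). Without root 2 the rise of ATPC2 is lost (adjusted p = 0.051).

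All 15 suberin and endodermis genes rose, CASP2 at least 1080-fold (median 8.15, or 7.91 with bounds, adjusted p = 2.82e-08, and adjusted p = 0.0207 with an estimated correlation). All 9 root hair genes rose, PRP3 at least 2310-fold (median 11.54, or 8.96 with bounds, adjusted p = 6.18e-08). Nutrient uptake genes rose in 15 of 18 cases, SULTR1;2 by 10.60 ± 0.76 (median 5.01, adjusted p = 2.19e-07). Both have adjusted p = 0.0156 with an estimated correlation. All 6 triterpene genes rose (median 14.62, or 12.78 with bounds, adjusted p = 2.41e-07, and adjusted p = 0.00438 with an estimated correlation). Hypoxia genes rose in 8 of 9, SUS4 by 6.77 ± 0.49 (median 3.53, adjusted p = 0.00314, and adjusted p = 0.162 with an estimated correlation). Secondary wall genes rose in 19 of 21, MYB46 by 3.22 ± 0.33 (median 2.67, adjusted p = 1.37e-06, and adjusted p = 0.192 with an estimated correlation). Lignin monomer genes rose in 12 of 14, 4CL2 by 4.43 ± 0.27, and F5H1 fell by 2.98 ± 0.23 (median 1.86, adjusted p = 0.00259, and adjusted p = 0.336 with an estimated correlation). Cell cycle genes rose in 14 of 20 (median 1.21, adjusted p = 0.0375, and adjusted p = 0.55 with an estimated correlation). That call is lost without mature rosette 1 (adjusted p = 0.126) or root 2 (0.0928).

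Wax genes fell in 9 of 14, CER2 by 7.49 ± 0.33, and KCR1 rose (median −4.43, adjusted p = 1.12e-05, and adjusted p = 0.116 with an estimated correlation). With only both organs fitted the rise of KCR1 is lost (adjusted p = 0.0506). All 5 guard cell genes fell, FAMA at least 1330-fold (median −8.96, adjusted p = 1.12e-05, and adjusted p = 0.0156 with an estimated correlation). Aliphatic glucosinolate genes fell in 9 of 12, CYP83A1 by 2.99 ± 0.36, and MAM3 and CYP79F2 rose (median −1.63, adjusted p = 0.00317, and adjusted p = 0.31 with an estimated correlation). With the clock score the rise of MAM3 is lost (adjusted p = 0.0723). Flavonoid genes fell in 8 of 13, and MYB12 rose (median −2.69, adjusted p = 0.0378, and adjusted p = 0.336 with an estimated correlation), a list call lost without root 3 (adjusted p = 0.112). Senescence genes fell in 7 of 12, PAO by 4.56 ± 0.33, and WRKY6 rose by 3.03 ± 0.34 (median −1.62, adjusted p = 0.0249, and adjusted p = 0.31 with an estimated correlation). Salicylate genes fell in 11 of 16, and EDS5 (2.25 ± 0.33) and FMO1 rose (median −4.65, adjusted p = 0.00715, and adjusted p = 0.241 with an estimated correlation). The rise of FMO1 is lost without mature rosette 2, 3 or 4 or any single root (adjusted p = 0.0726 to 0.112), with RLE scaling (0.053), no filter on low counts (0.0722) and DESeq2 (0.216). Phase change genes fell in 8 of 14, SPL3 by 4.58 ± 0.34, and SMZ (4.51 ± 0.52) and TOE2 rose (median −2.03, adjusted p = 0.0249, and adjusted p = 0.099 with an estimated correlation). Without root 1 the rise of TOE2 is lost (adjusted p = 0.0516). In all, 29 of 40 lists pass, 9 higher and 20 lower. Adjusted over the list alone, the counts given here do not change.

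Stems and flowers grew in the same light regime, so this comparison is free of the day-length difference from rosettes. Stems have more transcripts for the NDH complex, cyclic electron flow, photosystem I and photorespiration, with NDHL at 134 ± 22.1 CPM against 30.8 ± 5.06 (mean ± SD, n = 4 each), but these lists have adjusted p = 0.169, 0.169, 0.396 and 0.212 with an estimated correlation. They also have far more for secondary walls, lignin and aliphatic glucosinolates, such as CESA7 (745 ± 246 against 16.3 ± 4.44), with adjusted p = 0.169, 0.212 and 0.212 with an estimated correlation. Flowers have more for pollen, floral regulators, flavonoids and the cell cycle, such as the petal and stamen regulator PI (2.13 ± 1.08 in stems against 357 ± 128) and the flavonol gene FLS1 (5.14 ± 2.77 against 267 ± 67.5), with adjusted p = 0.109, 0.169, 0.296 and 0.169 with an estimated correlation.

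Between stem and flower 13485 genes differ, 6189 higher and 7296 lower, of which 3636 and 5689 by at least 2-fold. The largest increases are in RLP19 (chromosome 2, 6533261 to 6537002; 53.5 ± 31.4 CPM in stems against 0.0318 ± 0.0234), the galactinol synthase gene GolS2 (841 ± 138 against 1.57 ± 1.3) and ABCB16 (60.7 ± 14.4 against 0.149 ± 0.285). UMAMIT36 is at 29.5 ± 19.8 against 0.143 ± 0.154, GLR2.7 at 26 ± 1.35 against 0.141 ± 0.139, and WAK3 at 13.6 ± 5.68 against 0.0718 ± 0.0404 CPM. On the lower side, with 0 counts in stems, are CYP71B31 (chromosome 3, 19760475 to 19762357; 1047 ± 671 CPM in flowers, at least 66300-fold), the terpene synthase gene TPS10 (735 ± 339, at least 46700-fold) and the stamen regulator MYB21 (257 ± 122, at least 16100-fold). The nectary transporter gene SWEET9 (165 ± 66.1, at least 10100-fold) and the invertase gene cwINV4 (122 ± 73.6, at least 7680-fold) also have 0 counts, and AAE11 is at 0.0102 against 1178 ± 767 CPM.

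Nuclear NDH genes rose in 18 of 20 cases, with a median of 1.62 (adjusted p = 6.58e-08, and adjusted p = 0.169 with an estimated correlation), PNSL2 by 2.44 ± 0.18 and NDHN by 2.29 ± 0.28. PNSB3 (0.19) and PNSL5 (0.03) did not pass. All 16 photosystem I and LHCI genes rose, with a median of 1.3 (adjusted p = 3.24e-05, and adjusted p = 0.396 with an estimated correlation), LHCA2 by 2.11 ± 0.30. PGR5, PGRL1A and PGRL1B rose (median 1.29, adjusted p = 0.0162, and adjusted p = 0.169 with an estimated correlation), PGRL1A by 2.23 ± 0.17. Plastid NDH genes rose in 5 of 10 (median 1.62, adjusted p = 0.0104, and adjusted p = 0.321 with an estimated correlation), and NDH assembly genes in 4 of 10 (median 0.52, adjusted p = 0.047, and adjusted p = 0.467 with an estimated correlation). The assembly call is lost without flower 2 (adjusted p = 0.0766) or 3 (0.0655), or without stem 2 (0.0652), 3 (0.0521) or 4 (0.0926), with only both organs fitted (0.0611) and with library size as the only scaling (0.0529). All 11 thylakoid regulation genes rose, TAP38 by 1.91 ± 0.29 (median 1.35, adjusted p = 3.24e-05, and adjusted p = 0.0499 with an estimated correlation).

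Leaf-type ferredoxin and FNR genes rose in 5 of 8, LFNR1 by 1.38 ± 0.21 (median 0.63, adjusted p = 0.0492, and adjusted p = 0.321 with an estimated correlation). Without flower 2, 3 or 4 that list has adjusted p = 0.0849, 0.0655 and 0.0513, without stem 2 or 3 0.0664 and 0.0636, and with library size as the only scaling 0.0573. In the cytochrome list 4 of 8 rose, ATPG by 1.48 ± 0.20, and ATPC2 fell (median 0.71, adjusted p = 0.0492, and adjusted p = 0.467 with an estimated correlation). Without flower 2, 3 or 4 it has adjusted p = 0.0824, 0.0655 and 0.0558, without stem 2 or 3 0.0672 and 0.0704, with a replicate block 0.0529 and with the clock score 0.0575. The fall of ATPC2 is lost without flower 3 or 4 or stem 1 or 2 (adjusted p = 0.0562 to 0.0628), without both 4th libraries (0.0696) or stems 1 and 4 (0.146), and with only both organs fitted (0.0831). Photosystem II genes rose in 10 of 11, PSBO2 by 1.80 ± 0.18 (median 1.1, adjusted p = 0.00153, and adjusted p = 0.37 with an estimated correlation). LHCII genes rose in 10 of 15, LHCB7 by 1.89 ± 0.30 (median 1.28, adjusted p = 0.00321, and adjusted p = 0.467 with an estimated correlation). Calvin-Benson genes rose in 15 of 20, RCA by 2.21 ± 0.36 and CP12-2 by 2.47 ± 0.21 (median 1.06, adjusted p = 2.15e-05, and adjusted p = 0.321 with an estimated correlation). Photorespiration genes rose in 11 of 12, GLDP1 by 3.02 ± 0.42 (median 1.97, adjusted p = 1.49e-05, and adjusted p = 0.212 with an estimated correlation).

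Secondary wall genes rose in 20 of 21, IRX15 by 5.59 ± 0.32 and CESA7 by 5.52 ± 0.36 (median 3.79, adjusted p = 4.35e-11, and adjusted p = 0.169 with an estimated correlation). Lignin monomer genes rose in 13 of 14, COMT1 by 3.12 ± 0.25 (median 2.81, adjusted p = 2.97e-08, and adjusted p = 0.212 with an estimated correlation). All 12 aliphatic glucosinolate genes rose, BCAT4 by 4.12 ± 0.39 (median 3.18, adjusted p = 1.51e-06, and adjusted p = 0.212 with an estimated correlation), and 6 of 9 indolic ones, MYB51 by 3.42 ± 0.34 (median 1.19, adjusted p = 0.024, and adjusted p = 0.296 with an estimated correlation). None of the 9 seed storage genes passes, though the list does, upward, with a median of 2.18 (adjusted p = 0.0492, and adjusted p = 0.561 with an estimated correlation). Summed over the list, stems 1 and 4 are at 387 and 316 CPM, and flower 2 is at 152 CPM (other flowers 0.0421 to 1.33). The call is lost without flower 1 (adjusted p = 0.0828), 3 (0.0749) or 4 (0.111), or without stem 1 (0.103), 4 (0.116) or both (0.385), without both 4th libraries (0.249), with a replicate block (0.0607), the clock score (0.0625) and with only both organs fitted (0.105).

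All 16 pollen genes fell, PRF5 by 6.48 ± 0.48 (median −5.32, adjusted p = 2.11e-08, and adjusted p = 0.109 with an estimated correlation). Floral homeotic genes fell in 13 of 15, PI by 7.40 ± 0.62 (median −4.31, adjusted p = 0.000269, and adjusted p = 0.169 with an estimated correlation), while SEP4 rose by 3.11 ± 0.16. All 20 cell cycle genes fell, MCM7 by 4.95 ± 0.28 (median −3.37, adjusted p = 2.03e-10, and adjusted p = 0.169 with an estimated correlation). Flavonoid genes fell in 9 of 13, FLS1 by 5.69 ± 0.60 and CHS by 5.33 ± 0.58 (median −2.92, adjusted p = 0.00226, and adjusted p = 0.296 with an estimated correlation). Wax genes fell in 9 of 14, PAS2 by 2.03 ± 0.20, and CER3 rose by 0.82 ± 0.30 (median −1.1, adjusted p = 0.0298, and adjusted p = 0.467 with an estimated correlation). The wax list has adjusted p = 0.0621 without both stem 1 and stem 4, and the rise of CER3 is lost without flower 1 or 4 or stem 2 or 3 (0.0578 to 0.0899) and with library size as the only scaling (0.0795). Suberin and endodermis genes fell in 9 of 15, with GPAT5 at 0.102 ± 0.12 against 85.9 ± 33.2 CPM (median −4.26, or −2.06 with bounds, adjusted p = 0.0161, and adjusted p = 0.321 with an estimated correlation). CASP3 rose, with no count in flowers, a call lost without any single flower or without stem 1 or 3 (adjusted p = 0.0561 to 0.13), without stems 1 and 4 (0.075), with a replicate block (0.0577), only both organs fitted (0.0963), the clock score (0.0571) and DESeq2 (0.323). The C4-acid list (median 0.57, adjusted p = 0.336) and the circadian clock list (median 1.06, adjusted p = 0.336) did not pass here or in any other comparison. The clock list holds morning and evening genes, which can move oppositely. Its test of a common direction therefore cannot exclude a clock difference. In all, 23 of 40 lists pass, 17 higher and 6 lower. Adjusted over the list alone, 11 LHCII and 5 cytochrome genes rise and 1 clock gene does, against 2 over all genes, and other counts given here are unchanged.

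**Figure D4:**
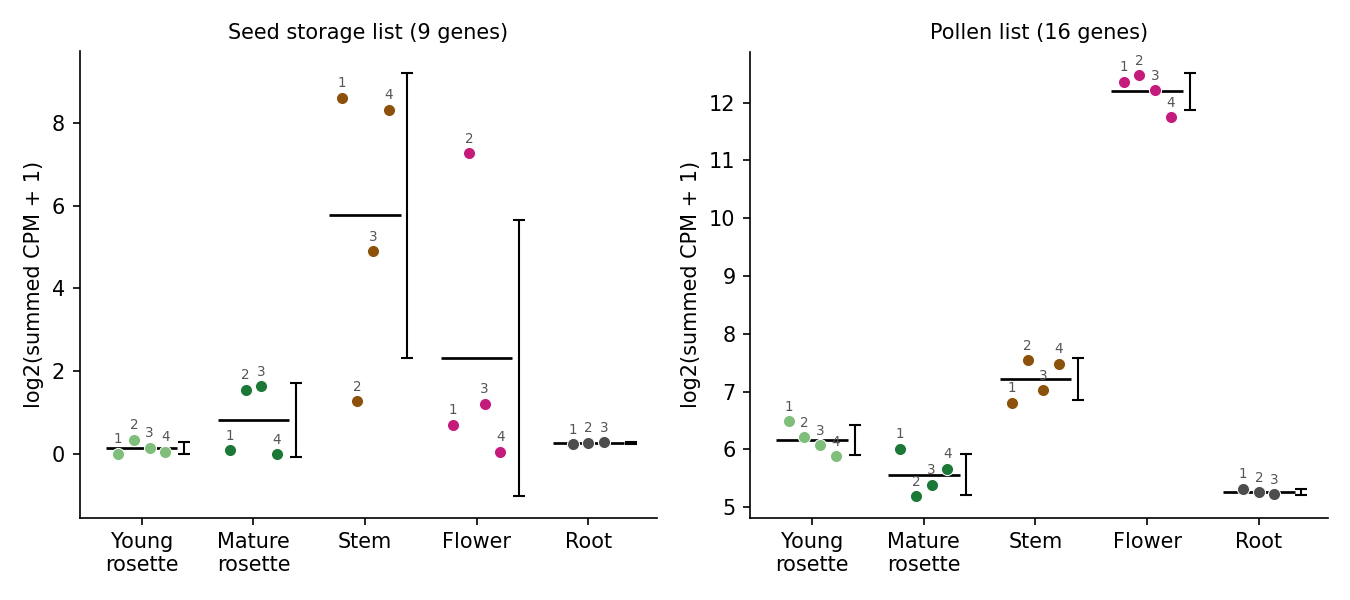
log2(summed CPM + 1) of 9 seed storage genes and of 16 pollen genes in each library (points numbered by replicate, black line for the organ mean, error bar for the SD). Seed storage transcripts are highest in stem 1 (387 CPM), stem 4 (316 CPM) and flower 2 (152 CPM) and low in stem 2 (1.42 CPM), and pollen transcripts are highest in flowers.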

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

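The tests on splits of the libraries and, among those on patterns below, the share of genes near the mature level, the test of harvest hour, the carry-over tests and all tests on pollen were chosen only after the result was seen. Single libraries were compared with the others of their organ in 92 sets of 4 libraries, and 10 have one library set apart by a gap above 0.829 of the range. Chance gives about 1 in 20.

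Mature rosette 1 accounts for 3 of them: NDHO at 245 CPM (others 122 to 125), NDHL at 243 (255 to 257) and RFNR1 at 13.8 (16.9 to 17.1). In flower 1, FD2 is at 863 CPM (435 to 465) and organellar genes take 0.132% of counts (0.0677% to 0.0764%). LFNR2 is at 360.0 CPM in flower 4 (169 to 194). PSAD1 is at 3940.0 CPM in young rosette 3 (3780.0 to 3790.0). Young rosette 1 has a total of 120458563 counts (29190041 to 39199121) and an NDH to photosystem I value of −4.28 (−4.14 to −4.13). CASP1 is at 0.041 CPM in stem 1 and 0 in the other stems.

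Mature rosette 1 is closer to the young rosettes than to mature rosettes 2 to 4. A mislabelled young rosette cannot be told from a mature one, since the tests part: with this library alone against 3 young ones, and the spread taken from the replicates of all organs, 43 genes are called at the least, where a young library calls up to 198, yet with the same young library left out it calls 1555 against 198, 44 against 0, 55 against 0 and 43 against 1, counts that hang on the library left out and carry little weight. Of the genes that separate both ages at least 24.0% lie nearer the mature level in it, against at most 14.5% in a young library. Another hour of harvest may account for the pattern: outside the clock list its deviation correlates across 23472 genes at −0.415 with that of stem 4 and −0.45 with that of flower 4, against −0.266 to 0.223 for the other stems and flowers with the 4th libraries out of the mean, where genes are not independent replicates. This does not tell harvest hour from another cause of a shifted clock. Mature rosette 1, stem 4 and flower 4 were set apart by clock scores that depart in opposite directions. Genes that follow the clock remained among the 23472. The age of the plants, as a biological difference, was not tested.

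Seed storage transcripts stand at 387, 28.7 and 316 CPM in stems 1, 3 and 4, and at 152 CPM in flower 2 (other flowers 0.0421 to 1.33). One carry-over of reads into all libraries is excluded, since the rosette mean is 0.148% of stem 1. Seeds or siliques in these samples could account for it, but cannot be told from other sources: a second list of late seed genes in stems 1 and 4 is at least 2.67 times that in stem 2, between the bounds of 2 and 5 set beforehand. That list is at 36.7, 7.27, 7.61 and 19.4 CPM in stems 1 to 4 and 24.1 in flower 2, and without OLEO4, a choice made after the values were seen, at 22.2, 0.437, 0.56, 12.7 and 7.78. No biological explanation was tested.

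Pollen transcripts in stems have a median of 2.5% of their level in flowers. Pollen on the stem samples may account for it: the upper quartile of the members' ratios is 1.44 times the lower, as a single source would give. Any other single source of pollen transcripts would give the same, so this span does not favour pollen on the samples. Carry-over of flower reads into stem libraries alone had no test of its own. For whole flowers or buds, the tapetum list decides nothing. Its median ratio is 5.11 times that of pollen, but with a wide span (quartiles 0.763% to 68.9%). AP3, PI and CRC reach at most 0.597%, below the lowest pollen gene at 1.11%. CYP71B31, TPS10, MYB21, SWEET9 and cwINV4 have 0 counts in all stems, against 1047, 735, 257, 165 and 122 CPM in flowers. They were picked as the largest falls, but any source with all flower transcripts at the pollen ratio would leave counts of them. This argues against flowers like those sampled, or their reads, as the source of the pollen transcripts. Buds that lack these transcripts cannot be told. One carry-over of flower reads into all libraries is excluded, as rosettes have 3.54% of the stem ratio. Expression in stem cells themselves was not tested.

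Each comparison was repeated, with only both organs fitted, over the 35 splits of its libraries. For genes called, only the real split, 1 of 35, reached the real count in each comparison: 10195 genes against at most 569 for stem and mature rosette, 6050 against 0 for young and mature rosette, 11283 against 333 for flower, 12032 against 4458 for root and 12475 against 0 for stem and flower. These shares are under 0.05, but 1 of 35 is the smallest share possible. The tests were chosen after the result was seen and not adjusted over the comparisons, so chance is unlikely rather than excluded. The other splits include some that keep most libraries of an organ together and so carry part of its difference, and 18 that share the organs out most evenly. For the nuclear NDH list chance is not excluded for stem against mature rosette (10 of 35 splits as low, 3 of them among the 18 even ones, real 0.000188, lowest other 2.08e-08). For young rosette (5 of 35, 0.000562 and 1.45e-06) and stem against flower (2 of 35, 9.77e-08 and 2.29e-08) the other splits as low all keep 3 libraries of an organ together, and the lowest even split has 0.0135 and 0.000368. The even splits alone are too few for a share under 0.05, so nothing is said on chance there. For flower (1 of 35, 1.67e-12 and 1.39e-09) and root (1 of 35, 1.64e-13 and 1.03e-07) only the real split is as low. This again makes chance unlikely rather than excluded. For the number of lists past the threshold, the real split of young rosette (1 of 35, 12 lists against at most 11) and flower (1 of 35, 28 against 27) stands alone by only 1 list, with at most 5 and 7 lists in the even splits. For stem against mature rosette (5 of 35, 19 against 21), root (2 of 35, 29 against 30) and stem against flower (4 of 35, 21 against 23) no even split reaches the real count, and nothing is said on chance.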

How the results depend on the processing

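The settings with library size only, the clock score, both 4th libraries left out and stems 1 and 4 left out were chosen only after the data were seen, the rest beforehand. Under RLE scaling, no filter on low counts, nuclear genes only, the fit on both organs only and DESeq2, the counts of genes called stay within 1.5 times those reported. Library size only shifts the median log2 change of all genes by 0.164 for stem, −0.266 for young rosette, 0.358 for flower and 0.57 for root against mature rosette, and by −0.193 for stem against flower. The share of called genes that are higher goes from 52.2% to 61.1%, 42.6% to 20%, 58.1% to 75.3%, 54.3% to 73.5% and 45.9% to 35.5% in that order. The nuclear NDH list for young against mature rosette then has adjusted p = 0.167, and with the replicate block 0.0503. That block calls 12850, 7658, 12391, 12784 and 13490 genes. The replicate numbers were not taken as pairs in the main fit. Of 36 pairs of libraries with the same number, 9 have a residual correlation across genes over 0.1. Their median is 0.033 (highest 0.292 for stem 4 and flower 4), against −0.012 in the 108 other pairs. Of 19 libraries 7 correlate best with one of their own number. A weak effect shared by replicates of the same number is therefore not excluded, and the block serves as an alternative. In the other alternatives that leave no replicate out, that list has 0.000562 to 0.0385, and 0.67 with an estimated correlation.

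With an estimated correlation in camera (limma), 0, 0, 8, 14 and 1 lists pass for stem, young rosette, flower and root against mature rosette and stem against flower, where 7, 2, 16, 18 and 8 have an unadjusted p under 0.05 and 19, 11, 27, 29 and 23 pass with the preset value. The nuclear NDH list then has 0.371, 0.67 and 0.169 for stem and young rosette against mature rosette and stem against flower, and holds in the others. Tested against a 2-fold change with glmTreat, 5806, 830, 6489, 7944 and 6466 genes are called in the same order. With the clock score as covariate 2687 genes are called between young and mature rosette, 2375 of them among the 7440, and LFNR2 turns to 0.108 there. In stem against mature rosette that covariate turns NDHV to −0.046 and NDHT to −0.104, and leaving out stems 1 and 4 turns NDHM to 0.158 and NDHN to 0.004. In stem against flower PNSL5 turns to −0.012 with RLE and −0.011 with DESeq2, and with library size only PNSL5 is at −0.171 and PNSB3 at −0.012. Of these genes only LFNR2 passes the test in the comparison named.

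For the NDH to photosystem I transcript ratio, medians give 1.08, 0.74 and 0.44 for stem against mature rosette, young rosette and flower, and a pseudocount of 0.1 gives 0.80 against root. With the replicate block the differences are 0.90, 0.64, 0.18 and −0.85 (exact sign-flip, adjusted p = 0.167 for the first 3 and 0.25 for root).

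Leaving out each replicate in turn gives 11659 to 14086, 5359 to 10060, 11362 to 12940, 11612 to 14323 and 12304 to 13239 genes in the same order, and 18 to 20, 8 to 12, 27 to 28, 28 to 29 and 19 to 24 lists. The nuclear NDH list has 8.85e-05 to 0.0021, 0.00837 to 0.161, 1.01e-13 to 3.17e-12, 5.64e-22 to 2.49e-18 and 2.04e-08 to 3.62e-07. The highest value for young rosette, 0.161, is without mature rosette 1. The ratio runs from 0.86 to 0.96 against mature rosette, 0.61 to 0.69 against young rosette, −1.2 to −0.69 against root and 0.11 to 0.23 against flower. PNSL5 in stem against flower runs from −0.033 to 0.122. Over all named genes, some of which were chosen for steadiness, 1667 such values keep direction and call, 55 lose the call, 3 gain it and 4 turn, and for the lists 855 keep and 29 lose it.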

Other observations

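The genes of this part, and the test of harvest hour, were chosen only after their values were seen. The C4-acid list passes in no comparison (adjusted p = 0.336 to 0.834), and young rosettes were not tested against roots, so most of what follows are values only. PPDK, which regenerates phosphoenolpyruvate, is at 847 ± 295 CPM (mean ± SD) in stems and 555 ± 300 in flowers, against 138 ± 70.5 in mature rosettes and 8.01 ± 1.03 in roots. Between stem and mature rosette it rose by 2.62 ± 0.43 (log2 change ± SE, adjusted p = 7.02e-05). The carboxylase gene PPC2 is at 1028 ± 11.7 CPM in young rosettes and 77.9 ± 37.3 in roots, and PPC3 at 18.9 ± 4.26 and 520 ± 132. The malic enzyme gene NADP-ME2 is at 1045 ± 69.1 CPM in roots and 73.9 ± 17.8 in young rosettes.

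In the thylakoid regulation list 1 of 11 genes, PTOX, rose in stems against mature rosettes and 5 fell (STN8, PBCP, VDE1, CURT1A and CURT1B), and the list did not pass (median −0.211, adjusted p = 0.397). The fall of STN8 is lost without mature rosette 1 (adjusted p = 0.191), stem 1 (0.0911), stem 4 (0.0731) or both 4th libraries (0.0789), with no filter on low counts (0.0506), a replicate block (0.055) and library size only (0.206). With only both organs fitted, or without stems 1 and 4, it has 0.161 and 0.229, and PTOX 0.08 and 0.133. The state-transition kinase gene STN7 is at 238 ± 39.3 CPM in stems and 178 ± 39.9 in mature rosettes, and PTOX, the plastid terminal oxidase gene, at 72.2 ± 8.03 and 55.9 ± 3.54. In flowers they are at 107 ± 32.2 and 38.2 ± 1.48. The most abundant transcript is LHCB1.3 in all 8 rosette libraries (2.06% to 2.62% of counts), PYK10, a glucosidase of ER bodies, in the 3 roots (2.02% to 2.32%), and RCA, for Rubisco activase, in stems 1 to 3 (0.915% to 1.44%).

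The clock score sets stem 4 (−1.75, others 5.44 to 6.88) and flower 4 (−2.71, others 4.06 to 4.3) apart, as it does mature rosettes 2 to 4. In roots it is 4.68, 4.44 and 2.5. A candidate explanation is that libraries of an organ were harvested at other hours. The value of −0.415 above, against −0.266 to 0.223 for the other stem and flower libraries, does not decide this. These libraries were picked by their clock scores, so genes that follow the clock could give such a value whatever shifted the clock. Harvest hours are not given in the sources used here.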
